A study of Lithospermum officinale with 3 samples.

How the data were processed

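Total RNA from leaf, stem and root of 2-year-old plants was extracted with a column kit, messenger RNA was captured on oligo(dT) beads, and libraries were made with a strand-specific kit, per the labels' protocols. The reads were paired-end with an average length of 101 bp, per the labels. There were 3 libraries, 1 per tissue. Whether the tissues came from the same plant is not stated in the sources used here.

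Trimmomatic and RSEM are named in the submitters' processing notes, without versions. The assembler, the aligner and its settings, and any annotation are not given in the sources used here. Per the file headers, each deposited library table holds for every unigene a length, an RSEM effective length, an expected count, a TPM and an FPKM. RSEM expected counts can be fractions, but 100% of the deposited expected counts were exactly whole in each library; whether the authors rounded them or left out reads with several targets is not known, so near-identical unigenes may share or lose reads. For unigenes with 20 or more counts, the deposited TPM and FPKM were within 2% of the values recomputed from expected count and effective length in 100% of cases, so TPM and FPKM carry no information beyond the counts and effective lengths. The deposited table merging the 3 tissues held the same FPKM and lengths, with 0 differences. No reference genome or annotation was used here. Gene lists for photosynthesis, naphthoquinone, phenylpropanoid, alkaloid and other pathways, cell wall, transport, housekeeping and non-plant sequences had been fixed, but they need gene names, which the files do not pair with unigene IDs, and no list was tested.

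Expected counts were entered as whole numbers. Library scaling factors came from the trimmed mean of M-values (TMM) in edgeR 4.0.16 under R 4.3.3, computed over the 3 libraries, and were 0.891 for leaf, 1.24 for stem and 0.903 for root. edgeR was used for these factors alone: its quasi-likelihood test was not run, since 1 library per tissue leaves no estimate of the spread. For each pair of libraries the ratio of scaled counts was given with an exact conditional binomial (Clopper-Pearson) 95% interval, computed with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 under Python 3.11.15. A unigene was counted as apart where the whole interval lay beyond 4-fold and the 2 libraries held at least 10 counts together. Expression was called at 1 TPM. Correlations used log2(TPM + 1), a scale that understates differences of low unigenes. Tau was computed on the same scale. A fold against a library at 0 was computed against 3 counts in that library.

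The interval calls were tested on simulated libraries with the real means and totals, in which 200 unigenes per comparison differed by known folds. In the leaf against root simulation, with 38203 unigenes tested, 64.0% of the unigenes 8-fold higher in leaf, 42.0% of those with a ratio of 0.125 and 100% of those 32-fold higher were found, and 0% of those 2-fold higher or unchanged. In the stem against root simulation, with 40723 unigenes, 60.0% of the unigenes 8-fold higher in stem, 60.0% of those with a ratio of 0.125 and 94.0% of those 32-fold higher were found. In the leaf against stem simulation, with 34745 unigenes, these were 50.0%, 36.0% and 92.0% for leaf over stem. The intervals held the true ratio for 96.6%, 96.4% and 96.7% of the unigenes in the same order. The simulated counts were Poisson draws with known scaling, which is the model that the interval assumes. Such coverage was therefore fixed by the design and checks the calculation only. The simulation held no spread between plants or libraries.

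The comparisons, thresholds, alternatives and the naming rule were chosen before the data were examined. Without gene names, that rule names the 2 unigenes each way in each comparison with the largest interval bound nearest to equality, among those at 100 TPM or more in the higher library, and the unigene of highest TPM in each library. The alternatives were DESeq2 1.42.0 size factors, total counts, upper quartile factors and deposited TPM as scales, other count filters, folds and pseudocounts, and thinning to the smallest total of 3490670. Scaling on totals without the 100 most counted unigenes, and thinning to 1432056 counts outside them, were added after seeing the data. The 100 most counted unigenes were left out of these thinned libraries. Point ratios of leaf to root in them were also added then. The TPM scale was applied as 1 factor per pair of libraries, the median over unigenes with 50 or more counts in both, so it leaves out the small differences in effective length between libraries. Thinning drew reads without replacement. Unigenes called in both leaf and stem against root were compared with 20 simulations of libraries without differences.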

Results

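Transcript abundance was measured by RNA sequencing in leaf, stem and root of *Lithospermum officinale*, a medicinal plant of the borage family. The plants were 2 years old and each tissue was represented by 1 library, so no value below carries a replicate error and no test between tissues was possible. The series title gives the aim as the search for genes of specialized metabolite synthesis. The measured features were 77047 unigenes, which are sequences assembled from the reads without a genome. Their median length was 565 nt, and their lengths ran from 196 to 12400 nt. A unigene is not necessarily a gene, since pieces or variants of 1 locus can be assembled apart. The files do not pair unigene IDs with gene names, so chromosome positions, gene functions and pathways were not analysed here, and unigenes are named by ID only.

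The root library held 10045956 expected counts, the stem library 4469828 and the leaf library 3490670, a 2.88-fold range. At least 1 count was recorded for 67492 unigenes in root, 62915 in stem and 55228 in leaf, and 935 unigenes had none in any library. The gap was widest among short unigenes: 69.8% of the unigenes of up to 300 nt had a count in root, 52.4% in stem and 35.1% in leaf. Of the unigenes over 2000 nt, 99.8% were detected in root, 99.9% in stem and 99.5% in leaf. A count of 0 allowed up to 0.859 CPM (counts scaled to the library total) in leaf, 0.671 in stem and 0.299 in root. Intervals and these limits cover counting error only, because each tissue had 1 library. Molecular identifiers were not used here, so reads copied from the same molecule could not be told apart.

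A few unigenes dominated every library, and a single 8690 nt unigene was the most counted in all 3 tissues. Its sequence was not used here, so whether it is a messenger, ribosomal or organellar RNA is open, and every share of a library total includes it. Unigene28437 held 34.4% of the root counts (95% exact binomial interval 34.34% to 34.39%), 19.6% of the leaf counts (19.58% to 19.66%) and 13.7% of the stem counts (13.67% to 13.74%). It was also the unigene of highest TPM in root, at 57122 TPM, against 21092 in leaf and 15218 in stem. The unigene of highest TPM in leaf and in stem was the 232 nt Unigene54060, at 55689 and 38448 TPM, compared with 21094 TPM in root. It ranked only 24th by count in leaf and 29th in stem, with 13724 and 11771 expected counts, and its RSEM effective length in leaf was 64.6 nt. The 100 unigenes most counted over the 3 libraries held 59.0% of the leaf counts, 43.5% of the stem counts and 56.7% of the root counts. Among these 100, 16 were over 4-fold higher in leaf than in root, 19 were over 4-fold higher in root, and 1 differed over 4-fold between leaf and stem.

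**Figure D1:**
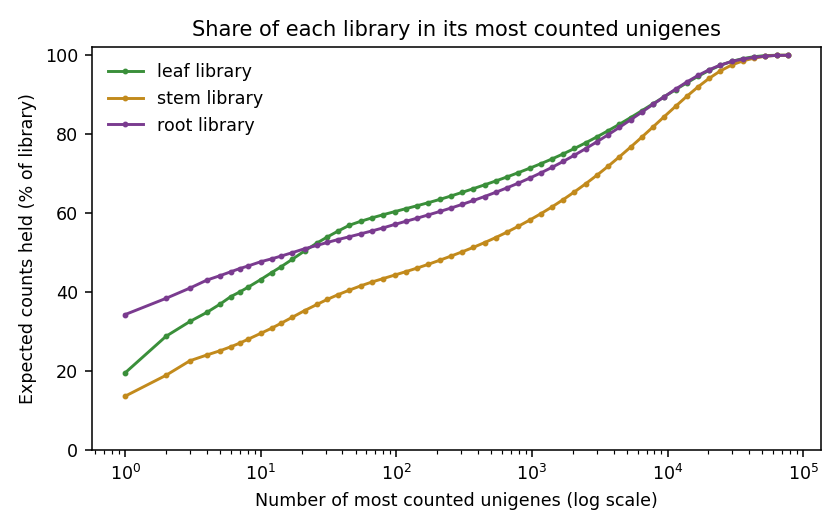
Share of expected counts (y axis, percent of the library) held by the most counted unigenes of each library (x axis, number of unigenes, log scale), with 1 line per library. The first point shows the single most counted unigene, at 34.4% of root, 19.6% of leaf and 13.7% of stem.

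Expression at 1 TPM or more was found for 60165 unigenes in root, 58675 in stem and 48607 in leaf. Of the 75271 unigenes that reached this level in at least 1 library, 34781 (46.2%) did so in all 3. The shared part was smaller at 5 TPM, with 9543 of 33575. The classes that follow are at 1 TPM. The shared pair classes were uneven, with 10595 unigenes in stem and root only, 8677 in leaf and stem only and 3342 in leaf and root only. Those found at this level in a single library numbered 11447 in root, 4622 in stem and 1807 in leaf. No minimum count was required for these classes. The median count over all unigenes was 6 in root, 5 in stem and 2 in leaf. Only 33201 unigenes in root, 30090 in stem and 23432 in leaf had 10 or more counts. With every library thinned to the smallest total, 56892 unigenes reached 1 TPM in stem, 52858 in root and 48526 in leaf, so leaf was still the lowest. With a floor of 10 counts and equal counts outside the 100 most counted unigenes, the numbers were 24071 in stem, 23334 in leaf and 21930 in root.

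Unigenes restricted to 1 tissue were far more frequent in root than in the shoot tissues. Restriction was defined as at least 1 TPM and 10 counts in 1 library and under 0.1 TPM in both of the others. Root held 877 such unigenes, stem 65 and leaf 4. They were weakly counted, with a median of 15 counts in root, and their median length there, 578 nt, was close to that of all unigenes. They made up 0.192% of the root counts. Only 55 of those in root, 6 of those in stem and 0 of those in leaf had 50 or more counts. Depth set much of the size of these classes, since thinning to equal counts outside the 100 most counted unigenes left 189 in root, 35 in stem and 14 in leaf. By the graded index tau on log2(TPM + 1), where 1 is expression in a single tissue and 0 is even expression, 13519 of the 75271 unigenes scored at least 0.85. Of these, 9552 were highest in root, 2884 in stem and 1083 in leaf. The numbers were 2695, 1175 and 435 among unigenes at 5 TPM or more in some library, and 8045, 4417 and 3816 after the same thinning. These tau calls required no minimum count. With 5 TPM and 10 counts required after that thinning, only 277, 61 and 26 remained. Root was highest in each of these counts, which set each tissue against both of the others. Between leaf and root alone, at equal counts outside the 100 most counted unigenes, 1022 unigenes were in leaf and not in root. The reverse held for 420. From all counts these numbers were 486 and 1839.

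Leaf and stem were the most alike of the 3 pairs. Across the 75271 unigenes at 1 TPM or more in some library, Spearman's rho of log2(TPM + 1) was 0.626 for leaf and stem, 0.317 for stem and root and 0.281 for leaf and root. Pearson's r was 0.734, 0.483 and 0.445 in the same order. These coefficients run across unigenes, which are not independent replicates. On CPM, which keep the effect of unigene length, rho was 0.868, 0.718 and 0.688, in the same order of pairs.

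Leaf, the main photosynthetic organ, was compared with root. Of 38203 unigenes with at least 10 counts over the 2 libraries, 2670 were higher in leaf and 789 were higher in root, with the whole 95% counting interval of the ratio beyond 4-fold. The 2670 leaf-high unigenes held 15.1% of the leaf counts and 1.38% of the root counts, and 211 of them stood at 100 TPM or more in leaf. The 789 root-high unigenes held 6.28% of the root counts and 0.445% of the leaf counts, and 172 of them stood at 100 TPM or more in root. No count was recorded in root for 436 of the leaf-high unigenes, or in leaf for 217 of the root-high ones.

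The leaf-high unigenes with the largest lower bounds at 100 TPM or more were Unigene45819 and Unigene70069. Unigene45819 (1348 nt) had 921 counts in leaf and 5 in root, a ratio of 537 (95% interval 229 to 1659), with 91 counts in stem. Unigene70069 (1165 nt) had 6546 counts in leaf and 105 in root, a ratio of 182 (150.0 to 223), and its level was 1732 TPM in leaf, 1022 TPM in stem and 14.9 TPM in root. At the root end, Unigene57388 (3006 nt) had 7408 counts in root and 0 in leaf, at least 846-fold higher in root when leaf is set to the limit of 3 counts. Unigene39992 (3809 nt) had 6903 counts in root and 1 in leaf, a ratio of 2366 with an interval of 424 to 93461. These intervals compare the 2 libraries, not the tissues. The bulk of unigenes lay toward root, with a median log2 ratio of -0.38 over the 20716 unigenes with 50 or more counts. It was -0.24 over the 38203 tested. Both floors apply to summed counts, so the deeper root library admits root-high unigenes at lower levels than leaf-high ones. The balance of leaf-high to root-high unigenes depended on the scale and the criterion: leaf-high unigenes made up 77.2% of those apart with TMM factors, but 53.0% (1882 against 1672) on the scale of the deposited TPM, which moved log2 ratios by a median of -0.65. It was also 53.5% (4366 against 3800) where a ratio of 4-fold was counted without an interval.

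**Figure D2:**
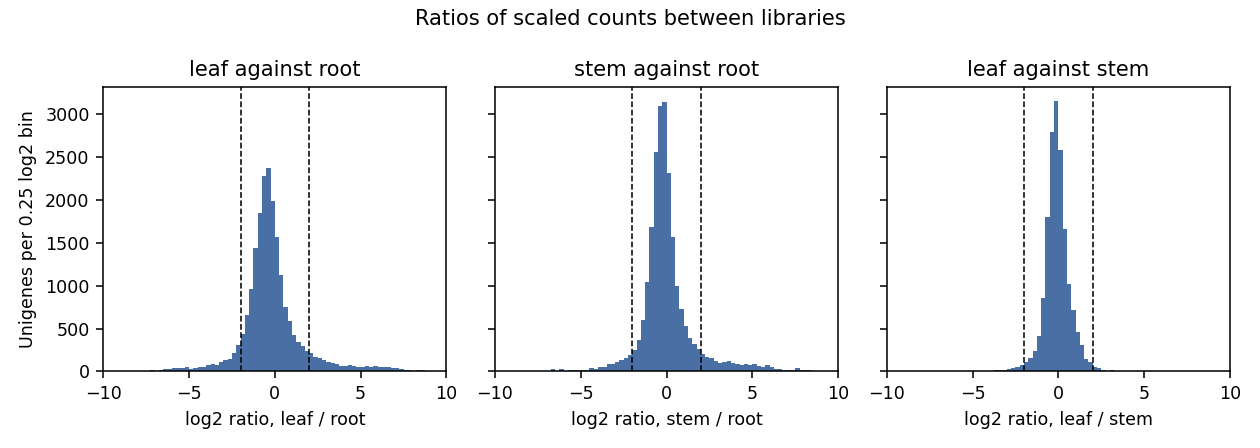
Distribution of log2 ratios of TMM-scaled counts for each pair of libraries (x axis) over unigenes with 50 or more counts in the pair (y axis, unigenes per bin), with 0.5 added to each count and dashed lines at 4-fold. The share of unigenes within 2-fold was 60.5% for leaf against root, 70.6% for stem against root and 86.1% for leaf against stem.

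The comparison of stem with root gave a similar number of unigenes apart. Of 40723 unigenes tested, 2477 were higher in stem and 766 were higher in root by the same criterion. The stem-high unigenes held 10.3% of the stem counts and 0.434% of the root counts, and the root-high unigenes held 5.04% of the root counts and 0.640% of the stem counts. Unigene69825 (3013 nt) had 1538 counts in stem and 3 in root, a ratio of 836 (95% interval 286 to 4061), and 164 counts in leaf. Unigene47485 (1658 nt) had 1505 counts in stem and 3 in root, a ratio of 819 (280 to 3974), and 74 counts in leaf. In the other direction, Unigene57388 was 239-fold higher in root (153 to 397) and Unigene57387 (2703 nt) was 223-fold higher (141 to 377), with 18 counts in stem, 6555 in root and 1 in leaf. Their numbers are consecutive and their root levels similar, at 368 and 365 TPM, so whether they come from separate genes is open. Stem-high unigenes made up 76.4% of those apart with TMM factors and 88.1% (3225 against 436) when libraries were scaled by total counts, which moved every log2 ratio by 0.46. At equal counts outside the 100 most counted unigenes, 1371 were higher in stem and 492 in root.

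Most unigenes that set leaf apart from root set stem apart from root in the same direction. Among 37564 unigenes tested in both comparisons, 1701 were higher than root in both leaf and stem, of 2479 in leaf and 2024 in stem. A further 471 were lower than root in both, of 789 and 766, and 0 differed in opposite directions. Independent lists of those sizes would share 134 and 16.1 unigenes. Simulated libraries with no difference between tissues gave no unigenes apart, so their overlap of 0 sets no level for these counts. The log2 ratios of the 2 comparisons correlated across unigenes at r = 0.886, against 0.328 in the simulated libraries, with a covariance of 3.08 against 0.0845. Both comparisons used the same root library, which cannot be split, so part of the excess overlap may come from it. The 1701 unigenes higher in both shoot tissues held 9.52% of the leaf counts, 9.19% of the stem counts and 0.373% of the root counts. The 471 unigenes higher in root than in both held 4.49% of the root counts, 0.228% of the leaf counts and 0.538% of the stem counts.

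The comparison of leaf with stem, the 2 organs of the shoot, gave few unigenes apart. Of 34745 unigenes tested, 73 were higher in leaf and 109 were higher in stem by the same criterion. The leaf-high set held 0.557% of the leaf counts and 0.0994% of the stem counts, and the stem-high set held 0.697% of the stem counts and 0.0474% of the leaf counts. Unigene45819 was 18.1-fold higher in leaf (95% interval 14.6 to 22.7), and Unigene1187 (1907 nt) was 16.5-fold higher in leaf (14.0 to 19.4), with 1528 counts in leaf, 166 in stem and 60 in root. Unigene39983 (991 nt) was 44.1-fold higher in stem (27.4 to 76.0), with 1341 counts in stem, 17 in leaf and 3962 in root, so root was its highest tissue. Unigene3723 (637 nt) was 32.1-fold higher in stem (21.3 to 50.9), with 1322 counts in stem, 23 in leaf and 11 in root. Over the 3 libraries, 63 unigenes were higher in leaf than in both of the others, 58 were higher in stem than in both, 25 were lower in leaf than in both and 4 were lower in stem than in both. With intervals beyond 2-fold the direction turned, to 629 higher in leaf and 579 higher in stem. The leaf share of the unigenes over 4-fold apart was 40.1% with TMM factors, 11.1% (32 against 257) with total counts and 10.3% (31 against 271) on the scale of the deposited TPM. Total counts moved every log2 ratio by -0.48 and deposited TPM by a median of -0.53.

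**Figure D3:**
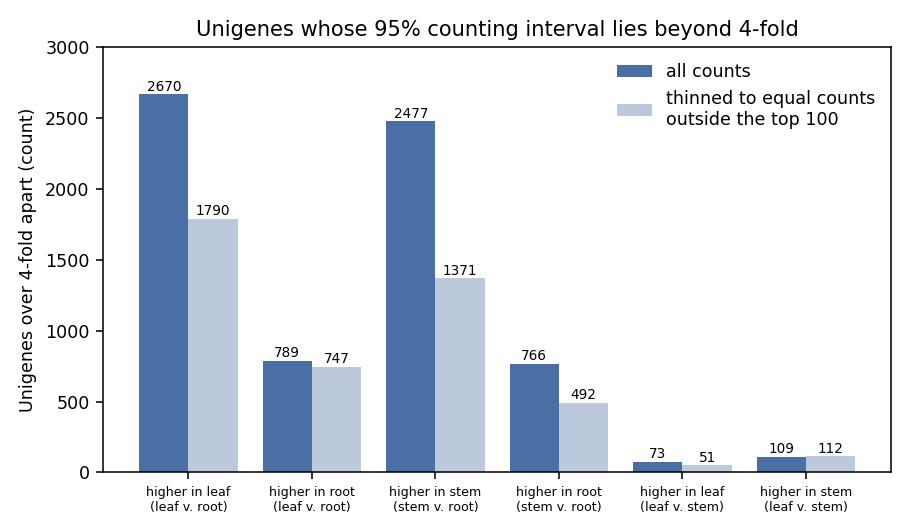
Number of unigenes (y axis) whose 95% counting interval lay beyond 4-fold in each comparison and direction (x axis), from all counts and after thinning the libraries to equal counts outside the 100 most counted unigenes. From all counts, leaf against root gave 2670 and 789, stem against root 2477 and 766, and leaf against stem 73 and 109.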

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

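Of 159 values recomputed under an alternative, 73 stayed within 1.5 times of the value reported (counts), within its exact binomial interval (shares) or within its Fisher interval across unigenes (correlations), and 86 moved. These limits differ greatly in width, so the tally does not measure robustness. All 24 correlations moved, since an interval across so many unigenes is very narrow and treats them as independent. Of 12 shares, the 6 that stayed were those on FPKM. Scaling on totals without the 100 most counted unigenes and thinning to equal counts outside them were chosen after seeing the data. With 1 library per tissue no replicate could be left out, and no paired analysis was possible because each tissue has 1 library. Other scales and filters for gene lists were not run, as the lists need gene names. The shares on FPKM equal those on TPM by construction, and depth limits all statements on absence. DESeq2 and upper quartile factors kept all counts of unigenes apart within 1.5 times. Unigenes apart by an interval beyond 2-fold numbered 4421 in leaf and 2632 in root (leaf against root), 4452 in stem and 2448 in root (stem against root), and 629 in leaf and 579 in stem (leaf against stem), where the majority passed from stem to leaf. Beyond 16-fold there were 742 and 119, 500 and 65, and 0 and 6 in the same order. A point ratio of 4-fold without an interval gave 4366 and 3800, 4452 and 2961, and 473 and 978. With 50 expected counts required, leaf over root fell from 2670 to 1413 and stem over root from 2477 to 1448. Root over leaf moved less, from 789 to 754, and root over stem from 766 to 616. The leaf share of unigenes apart between leaf and root was then 65.2%. Total counts as scale gave 436 higher in root than in stem, 32 higher in leaf than in stem and 257 higher in stem than in leaf. Deposited TPM gave 1672 higher in root than in leaf, 31 higher in leaf than in stem and 271 the other way. Upper quartile factors moved log2 ratios of stem to root by -0.12, and deposited TPM by a median of -0.12. Thinning to the smallest total left 1449 unigenes higher in stem than in root, and thinning to equal counts outside the 100 most counted left 1371, with 492 higher in root than in stem. Expressed unigenes in leaf, stem and root were 15334, 22529 and 22890 at 5 TPM, 23432, 30090 and 33201 at 10 counts, and 23334, 24071 and 21930 at 10 counts after thinning outside the 100 most counted. Restricted unigenes were 13 in leaf and 123 in stem with under 0.5 TPM in the others, 9 in leaf and 175 in root after thinning to the smallest total, 0, 6 and 55 in leaf, stem and root with at least 50 counts, and 14, 35 and 189 after thinning outside the 100 most counted. Tau calls at 5 TPM or more were 435 in leaf, 1175 in stem and 2695 in root, those after thinning outside the 100 most counted 3816 in leaf and 4417 in stem, and those with 5 TPM and 10 counts as well 26, 61 and 277. Spearman's rho for leaf and root, stem and root, and leaf and stem was 0.301, 0.337 and 0.636 without a filter, 0.312, 0.390 and 0.662 at 5 TPM, and 0.688, 0.718 and 0.868 on CPM. Pearson's r in that order was 0.253, 0.237 and 0.610 with pseudocount 0.1, where the order of the first pairs turned, 0.591, 0.664 and 0.835 with pseudocount 5, 0.460, 0.5004 and 0.741 without a filter, 0.387, 0.433 and 0.742 at 5 TPM, and 0.800, 0.847 and 0.939 on CPM. The top 10 unigenes held 43.2%, 29.6% and 47.7% of the counts of leaf, stem and root, against 30.1%, 20.9% and 18.3% of their TPM, and the top 100 held 60.5%, 44.5% and 57.3%, against 65.4%, 49.6% and 42.3% of TPM. Where a value moved and no cause is given, the cause was not tested.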

Other observations

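The tests of depth, of the scale between libraries, of the interval criterion and of leaf reads in the stem library were chosen after their results had been seen, and the class of even unigenes and the pairwise counts of presence after seeing the data. A class of evenly expressed unigenes was also counted. For 3359 of the 77047 unigenes the 95% counting intervals of all 3 pairwise ratios lay within 2-fold. Among the 17498 unigenes with 100 or more counts over the 3 libraries, 19.1% met this. They held 16.1% of the leaf counts, 20.4% of the stem counts and 15.1% of the root counts. Their median level was 8.04 TPM in leaf, 11.9 in stem and 13.4 in root. The class was not recounted on other scales, although deposited TPM moved log2 ratios of leaf to root by a median of -0.65.

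Presence in 1 tissue and absence in another was also counted for each pair of libraries, from all counts and at equal counts outside the 100 most counted unigenes. At equal counts there were 1022 unigenes present in leaf (1 TPM and 10 counts) and under 0.1 TPM in root, against 420 the other way. Stem against root gave 860 and 275, and leaf against stem gave 25 and 84. From all counts the direction against root was the opposite, with 486 in leaf and not in root against 1839 the other way, and 745 in stem and not in root against 1078. Leaf against stem gave 8 and 243 from all counts.

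Root held 877 restricted unigenes and leaf 4, although 2670 unigenes were over 4-fold higher in leaf than in root and 789 the other way. The depth of the root library accounts for part of this, since thinning to equal counts outside the 100 most counted unigenes left 189 in root and 14 in leaf. The ratio of root-restricted to leaf-restricted unigenes was still 13.5. Thinning leaves the set of assembled unigenes unchanged, so whether depth accounts for the whole cannot be told. Carry-over of reads between the leaf and root libraries is argued against, because some unigenes with 500 or more counts in 1 library had under 0.436% of that level in the other, in both directions. A candidate explanation is depth together with leaf transcripts shared with stem: with stem left out and the libraries thinned in the same way, unigenes in leaf and not in root were 243% as many as the reverse, but with stem left out alone they were 486 against 1839, so neither change by itself turned the asymmetry. The root-restricted unigenes may belong to root cells or to organisms on the root, which cannot be examined without sequences.

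Unigenes with far more counts in leaf than in root were also present in stem. For the 208 with 200 or more leaf counts and an interval beyond 16-fold over root, the median stem level was 44.7% of the leaf level, and the lowest was 4.12%. Leaf reads carried over into the stem library at 1 fixed share are argued against as the whole source, since 80.3% of the counting intervals excluded the median ratio and 24 unigenes had an interval above the leaf level. The interquartile range of the log2 ratios, 0.98, fell short of the bound of 1 set beforehand against leaf material or leaf reads in the stem library. That test therefore decided nothing, although the range was well above the median counting error of 0.09. Leaf material of another age in the stem sample cannot be told apart from expression in the stem. Neither sets a limit on that range, and there was 1 stem library. Expression of these transcripts by the stem is open and was not tested, as each tissue has 1 library.

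More unigenes were over 4-fold higher in leaf than in root than the reverse. The median log2 ratio was nevertheless toward root, at -0.38 over unigenes with 50 or more summed counts and -0.24 over all those tested. Leaf-high unigenes were still 70.6% of those apart after a single thinning to equal counts outside the 100 most counted unigenes. Unequal counts therefore do not account for the whole of the leaf excess among interval calls. Thinning leaves the set of assembled unigenes unchanged, so any effect of depth on that set was not tested. The interval criterion stays open. Without it the leaf share was 53.5% from all counts and 64.0% after the same thinning. The simulated leaf against root libraries returned 64.0% of 50 unigenes 8-fold higher in leaf but 42.0% of 50 higher in root. Stem against root had a similar split of 2477 against 766, with equal simulated recovery both ways. Each recovery rested on only 50 simulated unigenes, and the stem library was also shallower than the root library. The similar split therefore cannot decide whether the interval criterion contributes. The scale between libraries cannot be told apart from a difference between leaf and root themselves, which is untested: the leaf share was 53.0% on the deposited TPM, but moving the log2 ratios toward root lowers it by construction, and DESeq2 factors, total counts, upper quartile factors and totals without the 100 most counted unigenes gave 77.8%, 76.7%, 75.2% and 78.9%. The TPM scale rests partly on short unigenes with small effective lengths: those of up to 350 nt held 33.2% of the leaf TPM and 20.4% of the root TPM, but 3.59% and 1.47% of the counts.

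Unigenes with consecutive numbers had weakly correlated leaf to root ratios. It was hypothesized that neighbouring numbers hold pieces or variants of 1 locus, which would make counts of unigenes exceed counts of genes. Over 10637 consecutive pairs with 50 or more counts each in leaf and root together, the log2 ratios correlated at r = 0.280, against at most 0.0198 in 100 random orders, which lies between the bounds set beforehand for and against the hypothesis. Both members of 423 consecutive pairs were over 4-fold higher in leaf than in root, and both members of 112 were higher in root. Calls placed at random over all 77047 unigenes would give 92.5 and 8.08 such pairs. Those values include unigenes too weakly counted to be called and do not allow for any clustering of well-counted unigenes by number. The size of the excess therefore cannot be read as shared direction alone.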
